A study of Mus musculus with 2 samples.

How the data were processed

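Acetylation of histone H3 at lysine 9 (H3K9ac), a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in livers of mouse embryos of strain B6NCrl at embryonic day 11.5. The labels give 1 group of 2 biological replicates. Replicate 1 was made from the pooled livers of 109 embryos, and replicate 2 from a pool whose size the labels do not state. Both pools mixed male and female embryos, and both libraries carry a fragment size range of 300 to 500 bp in the labels. With 1 group there was no contrast between conditions. The comparisons were therefore between the replicates, between classes of genomic location, and between gene lists and the other genes of the genome.

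The deposited data were 4 peak lists in the ENCODE narrowPeak format on mouse build mm10 (GRCm38), per the labels and the README files beside them. The authors called peaks in each replicate alone and on the pooled alignments of both, and derived a replicated list from the pooled list and the lists of the replicates, per the README files. The peak caller, its version and the rule of replication were not given in the sources used here. The fold enrichment is a ratio that the authors' caller gave for each peak, in the column the format reserves for signal. The authors also deposited a −log10 p and a −log10 q per peak. These scores are the authors' own and were used only to describe, rank or filter peaks within a list. Per the README files, the list of replicate 1 was derived from 1 alignment file and 2 other files, and that of replicate 2 from 1 alignment file and 1 other file. The peak lists hold no read counts, so the sequencing depth of each library is unknown. No control reads or signal tracks were used here.

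Gene models came from GENCODE release vM21 on GRCm38, restricted to protein-coding genes on the chromosomes other than the mitochondrial one. This gave 21853 genes with 54361 distinct transcription start sites (TSSs). No peak ended past the end of its chromosome. A promoter peak of a gene overlapped the window of 1000 bp on either side of any of its TSSs. A distal peak overlapped no such window and was assigned to the gene of the nearest TSS within 50000 bp, counting all genes at a tie. Peaks were placed in TSS windows, in the rest of a gene or outside genes. Overlaps were computed with bedtools 2.31.1 at a minimum of 1 bp. Chance overlap came from 100 random placements of the peaks on their own chromosome. Shares are given with 95% Wilson intervals, which cover counting error only.

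Before the data were examined, 18 gene lists, the tests and a first set of alternative settings were fixed. The lists held globin, erythroid, heme synthesis, blood progenitor, megakaryocyte, macrophage and myeloid, hepatoblast, adult hepatocyte, endothelial, mesenchymal and mesothelial, neuronal, muscle, germ cell, Hox, imprinted, cell cycle, housekeeping and olfactory receptor genes. Ahsp of the erythroid list and H19, Meg3, Nespas and Kcnq1ot1 of the imprinted list were not analysed here because no protein-coding gene model carried these symbols. The share of each list with a promoter peak, or with a distal peak, was compared with that of all other protein-coding genes by a two-sided Fisher's exact test. The median width of the widest promoter peak per gene was compared with 100000 random lists of as many genes with a promoter peak, by a two-sided permutation test. A width needed at least 3 members with a promoter peak, which left out the germ cell and olfactory receptor lists in the replicated set with the window of 1000 bp. P-values were adjusted by the Benjamini-Hochberg method over the lists of each family, and an adjusted p below 0.05 was taken as passing. Fold enrichment and width of shared and single-replicate peaks were compared by two-sided permutation tests of the difference in medians with 100000 resamples. Peaks and genes are not replicates of the embryos, and neighbouring genes can share a peak, so these p-values describe the lists and not the variation between animals.

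The genes named in the text followed a rule fixed in advance. It took the 10 genes with the widest and the 10 with the highest promoter peak in the replicated list. It also took up to 4 members of each list with the widest promoter peak and up to 3 without one in alphabetical order. The globin genes and Alb, Afp, Ttr, Hnf4a, Prox1, Gata1, Klf1, Tal1, Runx1, Cdh5, Lhx2, Neurod1, Myod1, Ddx4 and Actb were always included. Genes that share a promoter peak with a named gene are given beside it. For any other gene outside the rule, the text says that it was chosen after its values were seen.

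The alternatives fixed in advance were an overlap of 50% of both peaks, a −log10 q of at least 5, equal numbers of top peaks, merged peaks, autosomes and X only, the pooled list, each replicate's list alone, TSS windows of 500 and 2500 bp, the most 5' TSS per gene, a distal reach of 100000 bp, list members found in no other list, and the bases covered by peaks within 5000 bp of a TSS. Genes were also divided into 3 equal classes of the promoter CpG ratio (observed over expected CpG within 500 bp of a TSS, highest TSS per gene), or of the spacing between TSSs, and tested within these classes by the Cochran-Mantel-Haenszel method. An overlap of 50% of either peak, and random lists matched on the CpG classes for widths, were added after the data were seen. The share of unique sequence at globin promoters was computed from 31-base words counted on both strands of the reference chromosomes, and was likewise chosen after the values were seen.

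The promoter and width tests of the lists were run on simulated peaks with known answers, over all 18 lists and 21853 genes. Each simulated gene had 1 TSS, the most 5' one, and the distal test was not run. A first simulation of 5 runs drew widths from all replicated peaks. In it 19 of 20 promoter tests of lists with a changed share passed, but only 3 of 5 tests of a list with widths multiplied by 2 and 2 of 5 with widths multiplied by 0.5. Of the tests of lists simulated without a change, 5 of 70 passed for promoter shares and 0 of 77 for widths. The simulation was then revised, after this result was seen, to draw widths from the widest promoter peak per gene over 20 runs. In the revised runs 80 of 80 changed promoter tests passed, as did 20 of 20 width tests at each factor. Of the tests without a change, 9 of 280 promoter tests and 3 of 313 width tests passed. Olfactory receptor genes, which lie in clusters with few other TSSs beside them, made up 5 of those 9. Simulated shares were 93, 15 or 100% against 58% elsewhere. The base share did not vary with CpG content, and no smaller change was simulated. These rates therefore need not hold for lists of unusual CpG content, for smaller differences or for genes with several TSSs. They do not cover the distal test.

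Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9.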

Results

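H3K9ac was profiled in 2 pools of mouse embryonic liver at day 11.5, a stage at which the organ holds hepatoblasts, the precursors of hepatocytes and bile duct cells, and large numbers of maturing red blood cells. The authors' lists held 61563 peaks in replicate 1, 42562 in replicate 2, 43802 in the pooled alignments and 32062 in the replicated set. These peaks covered 33.3, 25.7, 32.0 and 29.1 Mb of the genome. The median peak width was 287 bp in replicate 1, 342 bp in replicate 2 and 607 bp in the replicated set. Sequencing depth could not be read from the lists, and no interval below includes the error of read sampling.

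The first comparison asked how far the 2 replicates marked the same places. Weak sites were shared less often than strong ones. In both replicates the 10% of peaks with the highest −log10 p overlapped a peak of the other replicate in 100% of cases, whereas the 10% with the lowest did so in 12.6% of cases in replicate 1 and 25.6% in replicate 2. The most enriched promoter in the replicated set, that of the cytoskeletal actin gene Actb (chromosome 5, 142904559 to 142908801), reached 43.1-fold in each replicate's own list. Over all peaks, 45.9% of those of replicate 1 (95% interval 45.5 to 46.3%) and 72.1% of those of replicate 2 (71.7 to 72.5%) overlapped the other list, against 1.84% and 2.66% for peaks placed at random. Shared peaks were stronger and wider than peaks of a single replicate. In replicate 1 the median fold enrichment was 5.23 for 28269 shared peaks and 3.19 for 33294 others, and the median width was 607 bp against 228 bp. In replicate 2 it was 5.51 for 30695 shared peaks and 3.32 for 11867 others, with widths of 509 bp and 208 bp. Each of these 4 differences had a permutation p of 1e-05, the smallest that the resamples allow. Replicate 1 listed 1.45 times as many peaks as replicate 2. At a −log10 q of at least 5 the overlap rose to 78.0% of replicate 1 and 93.1% of replicate 2.

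**Figure D1:**
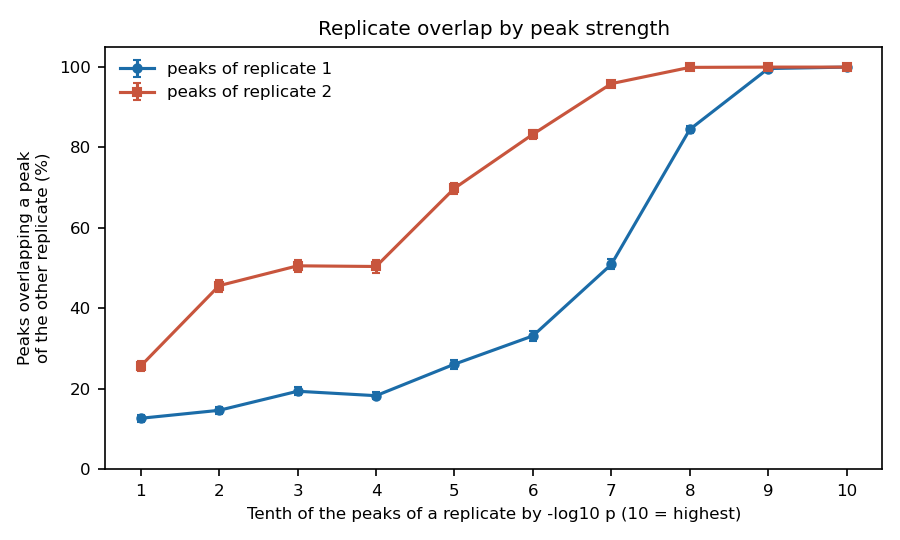
Share of peaks of each replicate (y axis, %) that overlapped a peak of the other by at least 1 bp, for 10 equal classes of peaks ordered by the authors' −log10 p (x axis, 10 is the highest), with 95% Wilson intervals as bars. The share rose from 12.6% in replicate 1 and 25.6% in replicate 2 to 100% in both.

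The replicated set was a selection from the pooled list. All 32062 replicated peaks were found in the pooled list with the same position and scores, and they made up 73.2% of it. Of them 78.3% overlapped a peak of both replicates, 13.9% a peak of replicate 1 alone, 5.42% a peak of replicate 2 alone and 2.38% a peak of neither. The 763 peaks of the last kind had a median fold enrichment of 3.08, against 6.42 for those that overlapped both. Because a share of the set rests on 1 replicate, values from a replicate's own list are given below where they changed a call or moved a called share or width, or a value of a named gene, by more than 1.5 times. Under a −log10 q of at least 5, 96.8% of replicated peaks overlapped both replicates.

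H3K9ac peaks gathered at gene starts. Of the replicated peaks 52.6% (95% interval 52.1 to 53.2%) overlapped a TSS window, 29.5% lay in the rest of a gene and 17.9% outside genes, while random placement put 3.69%, 38.4% and 57.9% there. Peaks at TSSs were the strongest and widest, with a median fold enrichment of 9.60 and width of 1052 bp, against 3.70 and 379 bp in the rest of genes and 4.00 and 432 bp outside genes. The TSS share was 33.7% in replicate 1 and 47.7% in replicate 2 (mean 40.7% ± 9.86, SD, n = 2), so the replicated set lay above both. At a −log10 q of at least 5 the share in the rest of genes fell to 16.1%. A promoter peak marked 12688 of 21853 protein-coding genes (58.1%). In the lists of single replicates 12409 genes were marked in both, 904 in replicate 1 alone and 360 in replicate 2 alone.

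The widest promoter peak covered 8000 bp at Irs2, which encodes an adaptor of the insulin receptor (chromosome 8, 11000978 to 11008977, 20.7-fold). It was followed by Ppp1r9b, which encodes the phosphatase scaffold spinophilin, with 7746 bp, Gse1 with 7532 bp, and Arid1a, which encodes a subunit of the BAF chromatin remodelling complex, with 7410 bp. A peak of 7180 bp on chromosome 11 (24075718 to 24082897) covered the start of Bcl11a, a repressor of globin genes, and of the neighbouring gene model A830031A19Rik. Nr2f2, a nuclear receptor gene, carried 7095 bp, Zfp36l1, an mRNA decay factor, 7037 bp, Klf16 6880 bp and Smim5 6879 bp. In replicate 2 alone the widest promoter peak was 3209 bp at Irs2, 3482 bp at Klf16 and 549 bp at A830031A19Rik, while that of Bcl11a still covered 6454 bp. The most enriched promoter was that of Actb with 51.5-fold, followed by Hnrnpu with 49.0-fold, the translation factor Eif4a2 47.8-fold, the splicing factors Srsf4 47.7-fold and Rbm39 46.9-fold, the splicing kinase Clk1 45.7-fold, the chromatin protein Hmgb2 44.8-fold and the RNA-binding protein Sfpq 44.4-fold. A single peak of 44.1-fold was shared by Rpl12, a ribosomal protein gene, and Lrsam1. In replicate 2 alone Eif4a2 reached 30.3-fold and Rbm39 23.3-fold.

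The next comparison asked which cell populations of the embryonic liver carried the mark at their promoters, with genes of other organs as controls. Red cell genes were marked almost throughout. Of 40 erythroid genes 37 had a promoter peak (92.5%, 95% interval 80.1 to 97.4%), against 58.0% of other genes (Fisher's exact test, adjusted p = 6.3e-06), and each replicate alone also marked 92.5%. Gfi1b, a repressor needed for red cell and platelet development, carried 6134 bp at 10.9-fold, and Slc4a1, the band 3 anion exchanger of the red cell membrane, 6024 bp at 16.1-fold. Tal1, a master regulator of blood formation, carried 5797 bp at 28.6-fold, Klf1, the erythroid Krüppel-like factor, 4015 bp at 33.4-fold (chromosome 8, 84900074 to 84904088), and Gata1 2691 bp at 11.5-fold on the X chromosome. The erythroid members with no promoter peak were Slc25a37, the mitochondrial iron importer mitoferrin, Car1 and Cd36. The share of unique sequence was not computed at these promoters, so a missing peak need not mean an unmarked promoter. All 9 heme synthesis genes were marked (adjusted p = 0.0195, Fisher's exact test), with Alad at 5973 bp and 20.5-fold and Cpox at 4411 bp and 34.6-fold. In replicates 1 and 2 alone the widest promoter peak covered 2476 and 1600 bp at Slc4a1 and 3416 and 2832 bp at Alad. Cpox reached 19.4-fold in replicate 1 and covered 2712 bp in replicate 2, and Gata1 reached 7.13-fold in replicate 2. Blood progenitor genes (20 of 28, adjusted p = 0.218) and megakaryocyte genes (15 of 21, adjusted p = 0.287) did not pass the same exact test. Progenitor promoters included Lyl1 with 22.5-fold, Ldb1 with 24.9-fold, Myb with 8.53-fold and Cbfa2t3 with 15.5-fold, and Runx1 had 14.9-fold. In replicate 2 alone Myb reached 12.8-fold. Flt3, Gfi1 and Cd48 had no replicated promoter peak. Among megakaryocyte genes Fermt3 reached 13.9-fold and the platelet integrin gene Itga2b 7.16-fold, and Clec1b, Gp6 and the thrombopoietin receptor gene Mpl had none. Gfi1 had a promoter peak of 3.27-fold in replicate 1 alone and Mpl one of 3.56-fold in replicate 2 alone.

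Liver lineage genes split by stage. Hepatoblast genes were marked in 33 of 43 cases (76.7%, 95% interval 62.3 to 86.8%, adjusted p = 0.0195 by Fisher's exact test), adult hepatocyte genes in 5 of 36 (13.9%, 6.08 to 28.7%, adjusted p = 2.6e-07). The hepatoblast result did not pass with replicate 2 alone (72.1%, adjusted p = 0.121, exact test) or at a −log10 q of at least 5 (58.1%). Of the 33 marked hepatoblast genes 4 had a promoter peak shared with another gene, and the list was not tested without them. The widest hepatoblast promoter peak was that of Dlk1, a surface protein used to sort hepatoblasts, with 3477 bp at 6.62-fold. Prox1, a regulator of hepatoblast migration, followed with 2969 bp at 7.39-fold, then Apoe with 2518 bp at 8.93-fold and Tbx3 with 2429 bp at 6.26-fold. Hnf4a, a master regulator of hepatocyte fate, had a promoter peak of 969 bp at 4.57-fold and Ttr, the thyroid hormone carrier transthyretin, one of 337 bp at 4.21-fold. In replicate 2 alone the widest promoter peak covered 1263 bp at Dlk1, 1593 bp at Apoe and 528 bp at Hnf4a. Alb, Afp and Apoc3, which encode secreted proteins of liver cells, had no replicated promoter peak, and Afp had one of 3.56-fold in replicate 2 alone. The marked adult genes included Glul, the glutamine synthetase gene, at 13.6-fold, whose peak also covered the start of Teddm2, and Fmo5, Gck and Ass1 at 9.96-, 3.25- and 6.23-fold. Glul reached 23.4-fold in replicate 2 alone. Aldob, Arg1 and Akr1c6 had none. The adult hepatocyte difference was lost within the classes of CpG ratio, where the share lay 4.27 percentage points below that of other genes.

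Other cell types of the organ stood between these. Of 28 endothelial genes 17 had a promoter peak (exact test, adjusted p = 0.850), among them Ets1 at 9.32-fold, Notch1 at 7.44-fold and Egfl7 at 12.4-fold, while the vascular cadherin gene Cdh5 had 467 bp at 4.93-fold and Emcn, Flt4 and Ecscr had none. Of 31 mesenchymal and mesothelial genes 22 had one (exact test, adjusted p = 0.227), with Hand2 at 3367 bp and Lhx2, a regulator of hepatic stellate cells, at 2490 bp, and Acta2, Bmp5 and Dcn had none. In replicate 2 alone the peak covered 282 bp at Cdh5 and 856 bp at Lhx2, and in replicate 1 alone Ecscr had a promoter peak of 4.03-fold and Bmp5 one of 3.05-fold. Macrophage and myeloid genes were marked less often than other genes (8 of 30, 26.7%, exact test, adjusted p = 0.0013), with Cebpb at 16.0-fold, Maf at 7.68-fold, Mafb at 6.05-fold and Cd14 at 4.40-fold, and no peak at the macrophage genes Adgre1, Aif1 and C1qa. Cd14 had 2.70-fold in replicate 1 and no promoter peak in replicate 2. Within the CpG classes the macrophage share lay 2.40 percentage points above that of other genes and did not pass.

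Genes of other organs were marked rarely. A promoter peak was present at 4 of 34 neuronal genes (11.8%, adjusted p = 2.17e-07), 6 of 33 muscle genes (18.2%, adjusted p = 8.04e-06), 2 of 30 germ cell genes (6.67%, adjusted p = 3.68e-08) and 1 of 1134 olfactory receptor genes (0.0882%), each lower than other genes by Fisher's exact test. The neuronal genes were Elavl4, Map2, Isl1 and Slc17a7, at 3.44- to 7.16-fold, and the germ cell genes Dazl at 6.42-fold and Dmc1 at 5.11-fold. Of the 6 muscle promoters 3 shared their peak with another gene, Mylpf with Tbc1d10b, Myl4 with Cdc27 and Myl3 with Pth1r, and the olfactory receptor gene Olfr56 shared its peak with Ifi47. Ryr1 had a peak of its own at 6.00-fold. Lists that passed as higher also held marked genes with a peak shared with another gene. These were 4 of 37 erythroid, 2 of 9 heme synthesis and 4 of 33 hepatoblast genes. Among imprinted genes it was 5 of 17, among cell cycle genes 3 of 30 and among housekeeping genes 7 of 30. In replicate 1 alone 23.3% of germ cell genes, 33.3% of muscle genes and 0.529% of olfactory receptor genes had a promoter peak, and in replicate 2 alone 6.67%, 24.2% and 0.176%. Isl1 reached 2.97-fold in replicate 1, and in replicate 2 Dmc1 reached 3.15-fold. Neurod1, Ascl1, Dcx, Elavl3, Myod1, Acta1, Actc1, Chrna1, Ddx4, Acrv1, Akap4, Bmp15, Olfr1, Olfr10 and Olfr1000 had none. Hox genes, which pattern the body axis, were marked in 14 of 39 cases (35.9%, exact test, adjusted p = 0.0102), with Hoxa2, Hoxb2, Hoxa5 and Hoxc4 at 5.72- to 10.8-fold and no peak at Hoxa10, Hoxa11 and Hoxa13. Replicate 1 alone marked 61.5% of Hox genes and replicate 2 alone 35.9%, and the pooled list with 46.2% did not pass (exact test, adjusted p = 0.139). Hoxa2 reached 3.53-fold in replicate 1 alone.

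Genes of dividing cells and general upkeep were marked throughout. All 30 cell cycle genes and all 30 housekeeping genes had a promoter peak (exact test, adjusted p = 4.08e-07 for each list), among them Ccnd3, Rrm2, Ccne2 and Ccnd2 at 28.2-, 28.9-, 34.4- and 13.4-fold, and Rps18, Gapdh and Rpl13a at 26.5-, 22.3- and 43.9-fold. Rps18 shared its widest promoter peak with B3galt4 and Vps52, and Rpl13a shared its own with Rps11. Within the CpG classes neither the cell cycle nor the housekeeping list passed, at 12.3 and 13.0 percentage points above other genes. The heme synthesis list did not either. Imprinted genes were marked in 17 of 20 cases (exact test, adjusted p = 0.0288), with Gnas at 5574 bp, Grb10 at 4528 bp and the growth factor gene Igf2 at 4295 bp, and no peak at Kcnq1, Magel2 and Ndn. Kcnq1 had a promoter peak of 2.93-fold in replicate 1 alone. The widest promoter peak covered 2572 bp at Grb10 in replicate 1 alone and 1693 bp at Igf2 in replicate 2 alone. With the most 5' TSS alone the imprinted share was 60.0% and did not pass, nor did the list pass within the CpG classes, at 2.24 percentage points above other genes.

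**Figure D2:**
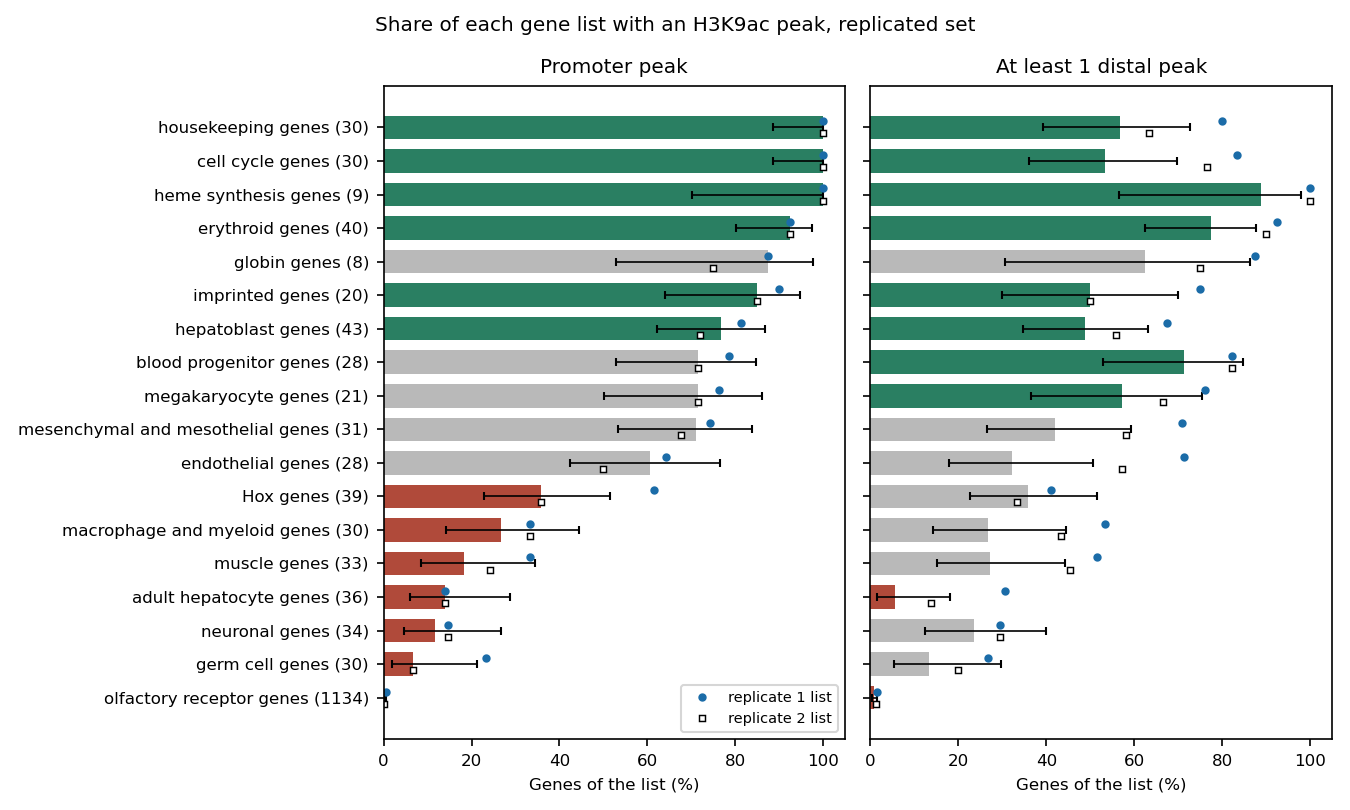
Share of each gene list (x axes, %) with a promoter peak (left) and with at least 1 distal peak (right) in the replicated set; the number of genes follows each name, bars are shares with 95% Wilson intervals, and symbols are the shares in the 2 replicates' own lists. Green bars were higher and red bars lower than all other genes at an adjusted p below 0.05, from 100% of heme synthesis, cell cycle and housekeeping promoters to 0.0882% of olfactory receptor promoters; grey bars did not pass.

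The distal comparison asked the same question of peaks away from every TSS window. At least 1 such peak was assigned to 5667 genes (25.9%). Several blood lists passed as higher. Of 40 erythroid genes 31 had a distal peak (77.5%, 95% interval 62.5 to 87.7%, Fisher's exact test, adjusted p = 1.17e-10), as did 8 of 9 heme synthesis genes (adjusted p = 0.000635), 20 of 28 blood progenitor genes (71.4%, adjusted p = 3.61e-06) and 12 of 21 megakaryocyte genes (57.1%, adjusted p = 0.0053). Slc4a1 had 8, Runx1 9, Cbfa2t3 10, Fech and Cpox 6 each and Gp9 7, while Klf1 had none. Hepatoblast genes had one in 21 of 43 cases (48.8%, exact test, adjusted p = 0.0035), with 5 at Tbx3 and 4 each at Dlk1 and Prox1, and adult hepatocyte genes in 2 of 36 (5.56%, adjusted p = 0.0070). Housekeeping genes (17 of 30, adjusted p = 0.0017), cell cycle genes (16 of 30, adjusted p = 0.0035) and imprinted genes (10 of 20, adjusted p = 0.0367) were also higher by the exact test, with 18 at Ccnd3, 10 at Actb and 9 at Igf2.

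The other lists passed as lower or did not pass. Olfactory receptor genes had a distal peak in 8 of 1134 cases (0.705%, exact test, adjusted p = 3.31e-135). Globin genes (5 of 8, adjusted p = 0.0521, Fisher's exact test), mesenchymal genes (13 of 31, adjusted p = 0.0928), germ cell genes (4 of 30, adjusted p = 0.200), Hox genes (14 of 39, adjusted p = 0.255), endothelial genes (9 of 28, adjusted p = 0.620), neuronal genes (8 of 34, adjusted p = 0.897), muscle genes (9 of 33, adjusted p = 0.897) and macrophage genes (8 of 30, adjusted p = 1) did not pass. In each replicate's own list the globin, endothelial and mesenchymal lists passed as higher, with endothelial shares of 71.4% and 57.1%, mesenchymal shares of 71.0% and 58.1% and globin shares of 87.5% and 75%. In replicate 1 alone, where the share of all genes also rose, from 25.9% to 48.7%, it was 30.6% of adult hepatocyte, 83.3% of cell cycle, 75% of imprinted and 1.59% of olfactory receptor genes, and in replicate 2 alone it was 13.9% of adult hepatocyte and 1.23% of olfactory receptor genes. The imprinted call was lost in replicate 2, and neuronal genes with 29.4% and germ cell genes with 26.7% passed as lower in replicate 1. At a −log10 q of at least 5 the share fell to 19.05% of megakaryocyte and 2.78% of adult hepatocyte genes, and neither passed. With a TSS window of 2500 bp the heme synthesis, megakaryocyte, hepatoblast, cell cycle, imprinted and adult hepatocyte calls were lost.

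In the replicated set erythroid genes had the largest median promoter peak width of the lists tested. The median width of the widest promoter peak was 2707 bp over 37 erythroid genes, against 1443 bp for random lists (middle 95% of lists 1135 to 1784 bp, permutation adjusted p = 0.00032). Cell cycle genes with 2202 bp (adjusted p = 0.0010) and housekeeping genes with 2158 bp (adjusted p = 0.0017) were also wider by the permutation test. The list medians were 2160 bp for 9 heme synthesis genes (permutation adjusted p = 0.0779) and 1837 bp for 20 blood progenitor genes (adjusted p = 0.121), which did not pass. Hepatoblast promoters were narrower, with 1035 bp over 33 genes (adjusted p = 0.0202), as were those of endothelial genes with 877 bp (adjusted p = 0.0190), Hox genes with 754 bp (adjusted p = 0.0060), megakaryocyte genes with 710 bp (adjusted p = 0.0027), 8 macrophage and myeloid genes with 443 bp (permutation adjusted p = 0.0010), 4 neuronal genes with 356 bp (permutation adjusted p = 0.0022) and 7 globin genes with 343 bp (permutation adjusted p = 0.00064). Mesenchymal genes with 1188 bp, imprinted genes with 1174 bp, muscle genes with 1092 bp and adult hepatocyte genes with 692 bp did not pass. In single replicates muscle genes passed as narrower in both, with 334 and 338 bp. Mesenchymal genes with 842 bp and imprinted genes with 735 bp did so in replicate 1, and adult hepatocyte genes with 410 bp in replicate 2. Heme synthesis genes with 2159 bp passed as wider in replicate 1 and blood progenitor genes with 1742 bp in replicate 2. The median fell to 367 bp for Hox genes in replicate 1, and in replicate 2 to 618 bp for hepatoblast, 268 bp for macrophage and 214 bp for neuronal genes. Against random lists matched on CpG class, a test added after the data were seen, the hepatoblast, endothelial, megakaryocyte and globin calls were lost and the erythroid, cell cycle and housekeeping ones passed. At a −log10 q of at least 5, 2 lists were narrower instead of 7. When all bases covered within 5000 bp of the TSS were counted, the medians of hepatoblast, Hox and globin genes lay above those of random lists without passing, at 1971, 2712 and 2235 bp, and the endothelial call was lost. By that measure heme synthesis genes with 6411 bp exceeded erythroid genes with 5090 bp. With the most 5' TSS alone the erythroid median was 2273 bp, close to 2186 bp for cell cycle and 2160 bp for heme synthesis genes.

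**Figure D3:**
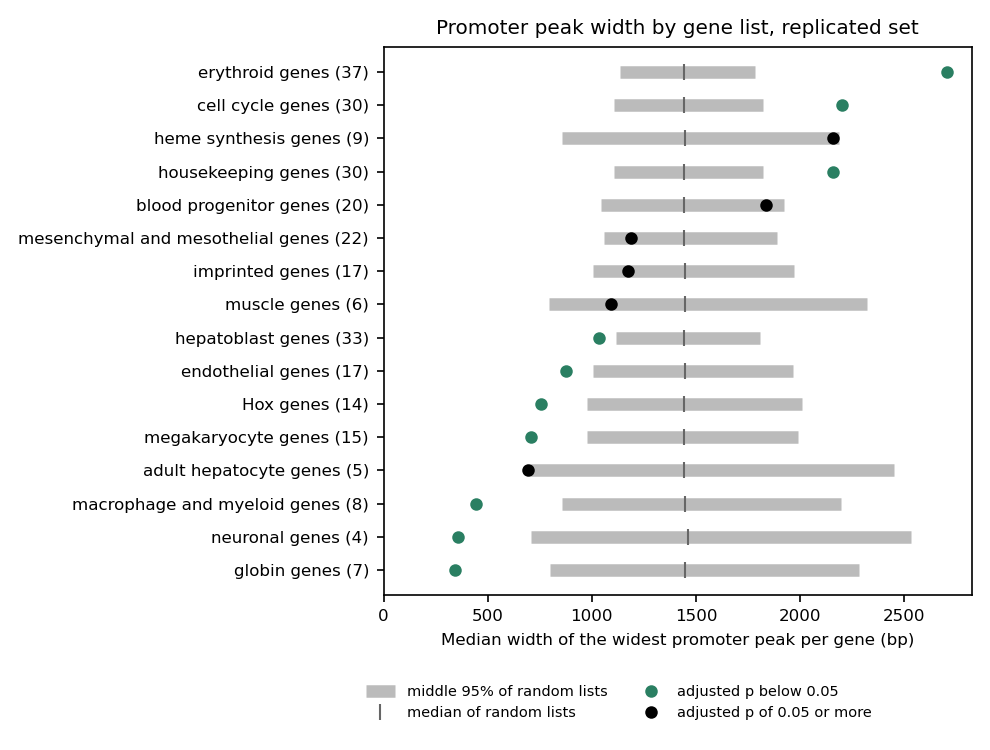
Median width of the widest promoter peak per gene (x axis, bp) for each gene list in the replicated set, with the number of genes that had a promoter peak after each name; grey bars are the middle 95% of 100000 random lists of the same size and ticks their medians, and green points passed at an adjusted p below 0.05 while black points did not. Erythroid genes lay furthest to the right at 2707 bp and globin genes furthest to the left at 343 bp.

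At the globin loci the replicated set held many short peaks and no wide promoter peak of a globin gene. Promoter peaks were present at 7 of 8 globin genes (adjusted p = 0.193, Fisher's exact test), at 3.70-fold for Hbb-bh1, 4.00-fold for Hbb-bh2, 4.21-fold for Hba-x, 4.55-fold for Hbb-bt, 4.66-fold for Hbb-bs and 5.11-fold for both Hba-a1 and Hba-a2. Some of these lay off the gene start. The peak counted for Hba-a2 (32297335 to 32297654) lay past the end of that gene. Upstream of their genes lay the peak of Hbb-bs (103828669 to 103828971) and the widest of Hba-a1 (32282472 to 32283002). With a TSS window of 500 bp, 4 of 8 globin genes had a promoter peak. Hbb-y, an embryonic beta-like globin gene, had no promoter peak but 7 distal ones. In replicate 2 alone Hbb-y had a promoter peak of 4.18-fold and Hbb-bh1 and Hbb-bh2 had none. The beta-globin genes with 50000 bp on either side (chromosome 7, 103762524 to 103903216) held 21 replicated peaks with a median width of 344 bp. The strongest reached 7.16-fold outside genes, with its summit 5679 bp from the TSS of Hbb-y (103858707 to 103859158). The alpha-globin window (chromosome 11, 32226400 to 32347298) held 37, and 21 had their summit in Nprl3, named after these values were seen, whose introns contain enhancers of the alpha-globin genes. The strongest of these, 25.6-fold, lay at the start of Nprl3 (32266689 to 32269094). The window around Alb and Afp (chromosome 5, 90410897 to 90558907) held 1 replicated peak, in an intron of Afp at 3.36-fold (90492291 to 90492649). Only 58.7% and 57.6% of the 31-base words at the starts of Hbb-bs and Hbb-bt, and fewer still at Hba-a1 and Hba-a2, occurred once in the genome, so peaks at these genes are uncertain. The share was at least 90% for the other 4 globin genes, Hba-x, Hbb-y, Hbb-bh1 and Hbb-bh2. All of these lay below the lower quartile of fold enrichment at TSSs, 4.89, or had no promoter peak, a check chosen after the values were seen. This check cannot tell how strongly or widely Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were marked, because their sequence is not unique.

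**Figure D4:**
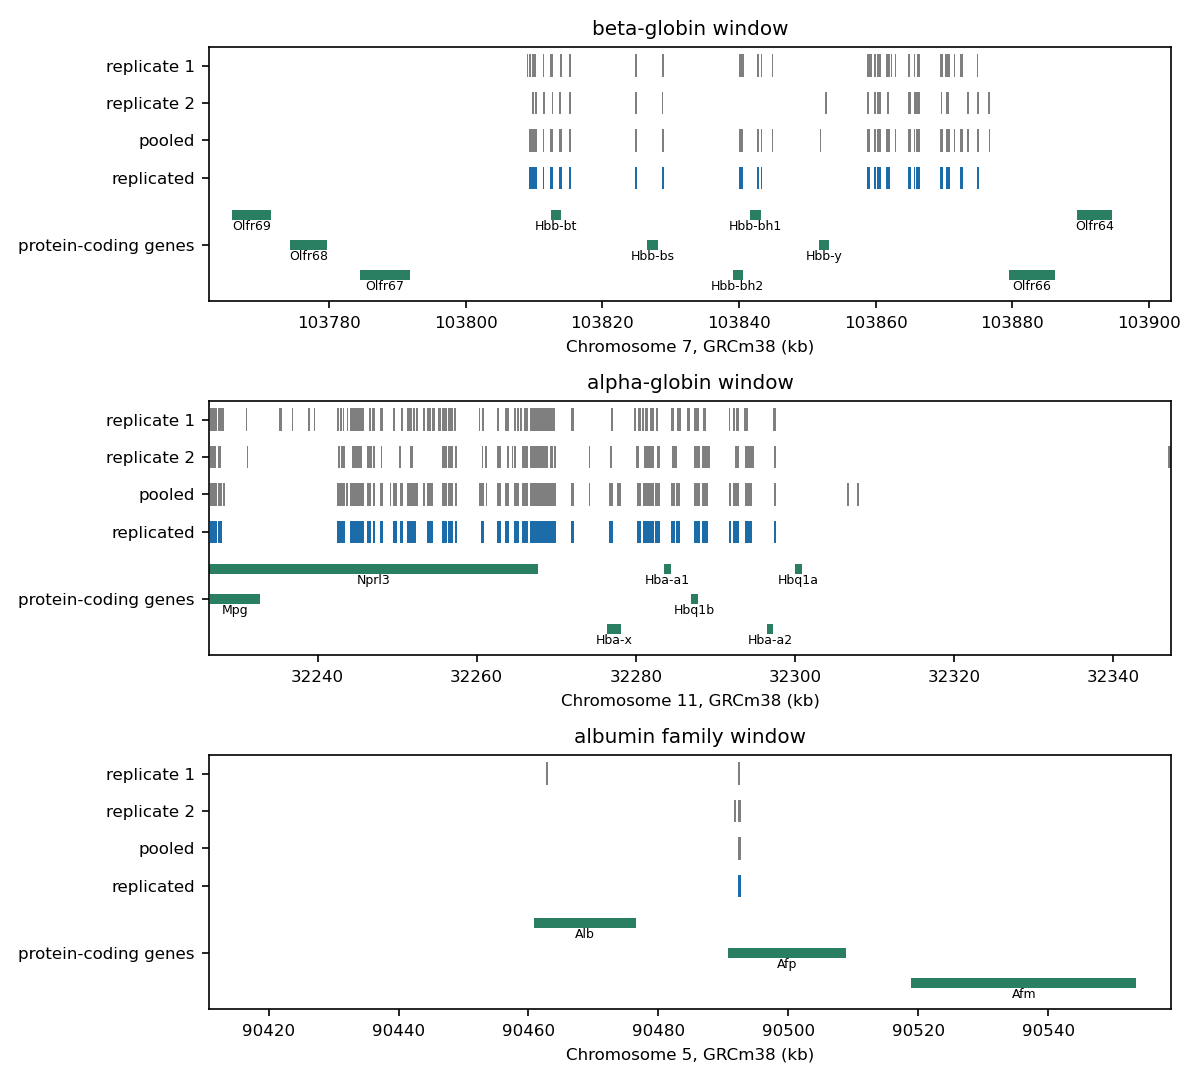
Peaks of each list in windows around the beta-globin, alpha-globin and albumin family genes (x axes, position in kb on GRCm38); blue blocks are replicated peaks, grey blocks the other lists and green bars protein-coding genes. The windows held 21, 37 and 1 replicated peaks.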

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

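Among the settings of this part, the tests chosen only after the result was seen were the overlap of at least 0.5 of either peak and the random lists matched on CpG class. The matched lists were chosen before their own values were seen.

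Values are given beside the result they replace, and the cause of a shift was not tested. Sequencing depth was not known, so no setting matched it between replicates.

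Leaving out replicate 2 or replicate 1, which keeps the other replicate's own list, gave 33.7 to 47.7% of peaks in TSS windows (52.6%), 33.2 to 43.9% in the rest of genes (29.5%) and 19.1 to 22.3% outside genes (17.9%). Promoter peaks ranged from 72.1 to 81.4% of hepatoblast genes (76.7%) and 50 to 64.3% of endothelial genes (60.7%), where the lower end reversed the direction. For Hox genes they ranged from 35.9 to 61.5% (35.9%), with the direction reversed at the upper end. Lists with fewer distal peaks numbered 2 to 4 (2). Distal peaks ranged from 75 to 87.5% of globin (62.5%), 57.1 to 71.4% of endothelial (32.1%) and 58.1 to 71.0% of mesenchymal genes (41.9%), which then passed as higher. Neuronal genes had 29.4% in both (23.5%) and germ cell genes 20.0 to 26.7% (13.3%), passing as lower without replicate 2, when other genes stood at 48.7%. Hox genes had 33.3 to 41.0% (35.9%), below other genes in both, and imprinted genes 50 to 75% (50%), no longer passing at the lower end. Lists with narrower promoter peaks numbered 9 to 12 (7). The 12, without replicate 2, include the germ cell and olfactory receptor lists at 195 bp each. These 2 lists had too few promoter peaks for a width in the replicated set. Median widths were 1702 to 2159 bp for heme synthesis (2160 bp), 1407 to 1742 bp for blood progenitor (1837 bp), 410 to 958 bp for adult hepatocyte (692 bp), 842 bp in both for mesenchymal (1188 bp), 334 to 338 bp for muscle (1092 bp) and 735 to 1263 bp for imprinted genes (1174 bp). The heme synthesis list passed as wider without replicate 2 and the blood progenitor list without replicate 1. The adult hepatocyte list passed as narrower without replicate 1, and the mesenchymal, muscle and imprinted lists did so without replicate 2, muscle also without replicate 1, where imprinted genes turned wider.

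With the pooled list, Hox promoter peaks rose to 46.2% and no longer passed. Distal peaks passed for globin (87.5%), endothelial (60.7%) and mesenchymal genes (54.8%).

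With peaks of a −log10 q of at least 5, 78.0% of replicate 1 (45.9%) and 93.1% of replicate 2 (72.1%) overlapped the other, and 96.8% of the replicated set overlapped both (78.3%). Locations became 70.4, 16.1 and 13.5%. Promoter peaks fell to 58.1% of hepatoblast, 47.6% of megakaryocyte and 46.4% of endothelial genes; the first no longer passed and the other two fell below other genes. In distal peaks 1 list was lower. Megakaryocyte (19.05%) and adult hepatocyte genes (2.78%) no longer passed, globin (50%) and mesenchymal genes (32.3%) passed, and muscle genes (12.1%) fell below others. In widths 2 lists were narrower: macrophage (1199 bp), hepatoblast (1394 bp), megakaryocyte (1040 bp), endothelial (1116 bp) and Hox genes (1254 bp) no longer passed, blood progenitor genes (2309 bp) passed as wider and mesenchymal genes (1662 bp) turned wider without passing.

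An overlap of at least 0.5 of both peaks gave 32.5% of replicate 1, 47.0% of replicate 2 and 59.1% of the replicated set, and 0.5 of either peak gave 77.5% of the replicated set. Equal numbers of top peaks gave 59.5 and 66.7%.

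With a TSS window of 500 bp promoter peaks fell to 50% of globin and 46.4% of endothelial genes, both below other genes. In distal peaks macrophage genes (26.7%) and muscle genes (27.3%) fell below others and mesenchymal genes (48.4%) passed, and the endothelial width (1116 bp) no longer passed.

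With a TSS window of 2500 bp, 21.5% of peaks lay in the rest of genes and the Hox promoter share (48.7%) no longer passed. In distal peaks 4 lists were higher (8) and 1 lower (2). Globin genes (62.5%) passed. Heme synthesis (55.6%), megakaryocyte (38.1%), hepatoblast (32.6%), adult hepatocyte (5.56%), imprinted (40%) and cell cycle genes (33.3%) no longer did. Macrophage (16.7%) and Hox genes (15.4%) turned lower and neuronal genes (20.6%) higher.

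With the most 5' TSS alone promoter peaks were found at 42.9% of endothelial genes, below other genes, and 60.0% of imprinted genes, no longer passing. In distal peaks endothelial (50%) and mesenchymal genes (48.4%) passed and macrophage genes (26.7%) fell below others. Blood progenitor widths (2094 bp) passed and Hox widths (1004 bp) no longer did.

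Within classes of CpG ratio the difference in promoter peaks, in percentage points, was 78.8 for globin, 40.6 for megakaryocyte and 17.9 for mesenchymal genes, which then passed. It was 25.5 for heme synthesis, -4.27 for adult hepatocyte, 2.24 for imprinted, 12.3 for cell cycle and 13.0 for housekeeping genes, which no longer did, and 2.40 for macrophage genes, where the direction reversed. Against lists matched on CpG class 3 lists were narrower, and the globin (343 bp), megakaryocyte (710 bp), hepatoblast (1035 bp) and endothelial (877 bp) widths no longer passed.

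Within classes of TSS spacing the distal difference was 40.5 points for globin genes, which passed, and 22.9 for imprinted genes, which no longer did. With a reach of 100 kb imprinted genes (50%) no longer passed and macrophage genes (26.7%) fell below others.

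With all bases covered within 5 kb of the TSS, 6 lists were wider (3) and 3 narrower (7). Heme synthesis (6411 bp), blood progenitor (3364 bp) and imprinted genes (2919 bp) passed as wider. Globin (2235 bp), hepatoblast (1971 bp) and Hox genes (2712 bp) turned wider without passing, and endothelial genes (1375 bp) no longer passed.

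Over all settings and lists 141 of 162 promoter, 123 of 162 distal and 115 of 144 width values kept their call and direction, as did all 8 of shared against single peaks. All 18 counts of promoter lists that passed stayed within 1.5 times the count in the report. For the named genes with a replicated promoter peak, the pooled list gives the same fold by construction, and 52 of 178 fold values of single replicates lay within 1 SD of the 2 replicates from it. For those without one, these lists also held none in 129 of 138 cases.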

Other observations

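The tests of depth and of control files were chosen only after the result was seen, those of embryo sex, weak peaks and random lists matched on CpG class after their pattern was seen but before their own values, and that of splitting in advance.

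The genes with the most distal peaks were chosen after their values were seen. Gse1 had the most with 29, then Rreb1, a zinc finger transcription factor gene, with 25, Trim8 with 24, Nol4l with 23 and Fam53b with 22. Zfpm1, which encodes the GATA1 partner FOG1, followed with 21 distal peaks, a widest promoter peak of 4979 bp and a highest promoter fold enrichment of 33.0. Smad6, an inhibitor of BMP signalling, had 20 and a promoter peak of 6404 bp, and Ccnd3, the cyclin D3 gene used in red cell maturation, had 18.

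The share of genes with a promoter peak rose with promoter CpG content. In the class with the lowest CpG ratio 8.77% of 7284 genes had a promoter peak, with a median width of 719 bp. In the middle class 72.0% and in the highest 93.4% did, with widths of 1179 and 1700 bp. All 7 globin genes with a promoter peak lay in the lowest class, as did 14 of the 37 erythroid genes with one. Against this background globin promoters were marked 78.8 percentage points, and megakaryocyte promoters 40.6 percentage points, more often than other genes of their class. Peaks at Hba-a1, Hba-a2, Hbb-bs and Hbb-bt are uncertain, as given above. With a TSS window of 500 bp, 4 of 8 globin genes had a promoter peak, against 57.4% of all genes. At a −log10 q of at least 5, 10 of 21 megakaryocyte genes had one, against 53.7% of all genes. Neither setting was tested within the CpG classes.

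The first pattern was that replicate 1 listed more peaks than replicate 2. Among peaks with a −log10 q of at least 5 the ratio fell from 1.45 to 1.11, and at a fold enrichment of 8 to 10 the median −log10 p was 23.4 in replicate 1 and 18.2 in replicate 2. Both are consistent with a lower sequencing depth in replicate 2. A difference between control files cannot be told apart from this, because the list of replicate 1 names 2 files other than alignments and that of replicate 2 names 1, and no control reads were used here. No biological explanation was tested.

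The second pattern was that the excess was missing on chromosome X, with 895 peaks in replicate 1 and 927 in replicate 2, a ratio of 0.966 against 1.46 on the autosomes (Fisher's exact test, p = 3.87e-18). A lower depth in replicate 2 was predicted to leave more peaks in replicate 1 on X as well, and the ratio of 0.966 missed this prediction. That ratio is also the pattern itself, so it is no separate test and cannot decide on depth. At a −log10 q of at least 5 the ratios were 1.13 on X and 1.11 on the autosomes. A larger share of male embryos in replicate 1 cannot be told apart: over shared peaks the median log2 ratio of fold enrichment on X minus that on autosomes was 0.0041 (95% bootstrap interval -0.04 to 0.05), but a control with the same mix of sexes would cancel such a shift. At a −log10 q of at least 5 the ratio on X was 1.02 times that on autosomes (95% interval 0.892 to 1.17), so the pattern may lie in weak peaks.

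The third pattern was that hepatoblast promoter peaks were narrower and erythroid ones wider than those of random genes. Erythroid promoters stayed wider, at 2707 bp, than lists matched on CpG class, whose middle 95% ended at 1506 bp, which argues against CpG content as the cause there. The hepatoblast median of 1035 bp lay inside the matched range of 787 to 1454 bp, so CpG content may account for it. Splitting of wide domains by the caller also stays open, since hepatoblast genes had a median of 1971 bp covered within 5000 bp of the TSS, inside the range of random lists. The share of hepatoblasts and red cells in the tissue was not measured and remains an untested biological explanation.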
